A study of Mus musculus with 7 samples.

How the data were processed

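Total RNA from 7 transplanted mouse tumours was biotin-labelled by the standard Affymetrix procedure and measured on 1-colour expression arrays, per the labels' protocols. Per the same protocols, the tumours had been frozen in liquid nitrogen and the RNA extracted with Trizol. Sample titles assign 3 arrays to the Met1 tumour line and 4 to the DB7 line and number the samples within each line. The series' design text describes tumours of first-generation outcrosses, whereas the sample labels name transplant tumours of these lines. The sample labels were followed. Nothing in the labels states that each array came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

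The deposited values are log2 probe set summaries, as judged from their range and distribution, and the authors' log base is not stated in the sources used here. The submitters' processing notes name RMA and MAS5 without saying which gave the values. The deposited columns had closely similar medians and quartiles but were not identical in distribution, and they were used as deposited. The software version, the background correction and the detection calls are not given in the sources used here. Summaries of this kind can compress large differences near the floor and the ceiling, so the fold of a gene that lies below the array median in either group is approximate. The number of arrays limits the precision of every value.

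The table held 22690 probe sets. The 64 control probe sets were left out of the tests, which left 22626. GEO's platform annotation gave exactly 1 gene symbol to 20380 of these, several to 691 and none to 1555. Entrez identifiers of 20364 annotated probe sets (controls not included) were found in the RefSeq gene table of assembly GRCm38.p6, and no symbol needed updating. A probe set was tested where its value lay above the array's median on at least 3 of the 7 arrays, which kept 11704 probe sets. The tested probe set with the highest mean over the 7 arrays stood for its gene, which gave 7482 genes. Of the 2305 genes with several tested probe sets, 16 had probe sets that passed the threshold in both directions.

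Met1 and DB7 were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, all 7 arrays, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are Met1 minus DB7 on the log2 scale with their moderated standard errors (SE), and adjusted p-values are limma's. The 30 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Lists were tested with camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. An exact permutation test of each list's mean over the 35 ways of dividing the 7 arrays into 3 and 4 was added after the data had been examined. It counts absolute differences (two-sided), and the smallest p it allows is 0.0286.

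Genes named are the 12 with the largest difference in each direction among those past the threshold whose values did not overlap between the groups. Up to 4 members of each list with the smallest p, and Sipa1, Rrp1b, Krt8, Krt18, Krt5 and Krt14, were also named. Krt14 did not pass the intensity filter, and 1 further item of this rule is not reported here. List members named outside this rule were chosen after their values were seen: Ccne1, Stat5a, Csn2, Csn3, Csn1s1, Mfge8, Elf5, Muc1, Foxa1, Oas2 and Ifit1. So were Jchain, Glycam1, Cd79a, Cd79b, Ms4a1, Pou2af1, Cd2 and Cd3g.

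Alternatives covered normalization between arrays, the intensity filter, the variance model, array weights, a 2-fold minimum, probe sets open to cross-hybridisation, the choice of probe set per gene, each array left out in turn and the replicate number as a block. Leaving out the arrays DB7 1 and DB7 4 was added after the data had been examined. The fit was tested on simulated data with the overall mean and pooled within-group SD of each of the 11704 probe sets, drawn independently, of which 200 were changed. In this simulation, 68% of probe sets changed 1.5-fold, 94% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 8-fold were recovered in the right direction, and 4.79% of calls were false. It left out unequal spread of the groups and correlation between genes, and changed far fewer probe sets than the real comparison called. Its rates therefore need not hold for the real comparison. The search for runs of neighbouring genes found 0 windows in a simulation without a run and all 40 genes of a planted run shifted by 0.6.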

Results

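Gene expression was measured in transplanted tumours of Met1 and DB7, 2 mouse mammary tumour lines derived from animals carrying a polyoma middle T transgene. Met1 is known as a line that metastasises readily and DB7 as a line that seldom does. The comparison asks how basal expression differed between the 2 kinds of tumour. It cannot separate metastatic behaviour from any other difference between the lines, including any in the form of that transgene. Arrays of the same line were closely similar, with correlations across probe sets of 0.994 to 0.996 among the 3 Met1 arrays and 0.986 to 0.992 among the 4 DB7 arrays. Correlations between the lines lay between 0.967 and 0.972. The median within-group SD of a probe set was 0.09 in Met1 and 0.14 in DB7 on the log2 scale. The 3' minus 5' difference of the Gapdh control probe sets, a measure of RNA integrity, was -0.28 ± 0.05 in Met1 (SD, n = 3) and -0.25 ± 0.06 in DB7 (SD, n = 4; exact permutation test, two-sided, p = 0.514). For the Actb controls it was 0.41 ± 0.04 and 0.43 ± 0.10 (SD, n = 3 and 4; exact permutation test, p = 0.771).

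Met1 tumours carried high levels of milk protein transcripts such as Lalba and Wap, and DB7 tumours high levels of genes such as Wfdc2 and Comp. Clca3a2, a chloride channel accessory protein, was 72.1-fold higher in Met1, at 10.43 ± 0.21 against 4.26 ± 0.33 (log2, SD, n = 3 and 4; limma, adjusted p = 9.96e-08). Lalba, the milk protein alpha-lactalbumin, was 50.3-fold higher, at 12.61 ± 0.30 against 6.96 ± 0.08 (adjusted p = 3.9e-08). Igfbp5, a binding protein of insulin-like growth factors, differed by 5.65 (SE 0.23), and its other tested probe set by 2.68. Wap, the whey acidic protein, was 31.3-fold higher, and Ltf, the iron-binding milk protein lactoferrin, was 22.2-fold higher. Muc15, a mucin of the milk fat membrane, was 29.8-fold higher and Cldn7, a tight junction claudin, 21.1-fold higher. Mup5, Sectm1a, the acute-phase gene Saa1, Lao1, an amino acid oxidase of milk, and the nucleoside transporter Slc28a3 completed the 12 largest rises, at 18.3-fold to 30.2-fold. Slc28a3 differed by 4.19, and its other tested probe set by 2.73. Mup5, Saa1, Sectm1a and Clca3a2 have close relatives in the genome, so signal of a paralog cannot be excluded at their probe sets.

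In DB7 the largest excess was that of Wfdc2, a secreted protein with a whey acidic protein domain, at 10.46 ± 0.25 against 5.93 ± 0.44 in Met1 (log2, SD, n = 4 and 3; 23-fold; limma, adjusted p = 1.55e-06). Comp, a cartilage matrix protein, and Snorc, a proteoglycan of cartilage, were 21-fold and 22.9-fold higher in DB7. Prom1, a membrane glycoprotein used as a progenitor marker, was 12.3-fold higher, and Pglyrp1, a peptidoglycan recognition protein, 11.6-fold higher. The sialyltransferase gene St6galnac2 was 21.2-fold higher, while its other probe set differed by -0.78. Bpifa2, a secretory protein of the parotid gland, was 18.9-fold higher with a wide spread (9.84 ± 1.40 against 5.60 ± 0.97, n = 4 and 3; adjusted p = 0.00227). Gm6958, the transporter Slc47a1, the ketone body enzyme gene Bdh1 and B4galnt2 were 8.37-fold to 10.6-fold higher. The other tested probe sets of Gm6958 and B4galnt2 differed less, by -2.08 and -1.12. Ctse, cathepsin E, was 7.35-fold higher by the brighter of its probe sets and did not differ by the other (difference 0.0014), so its direction rests on 1 probe set whose sequence other transcripts share.

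**Figure D1:**
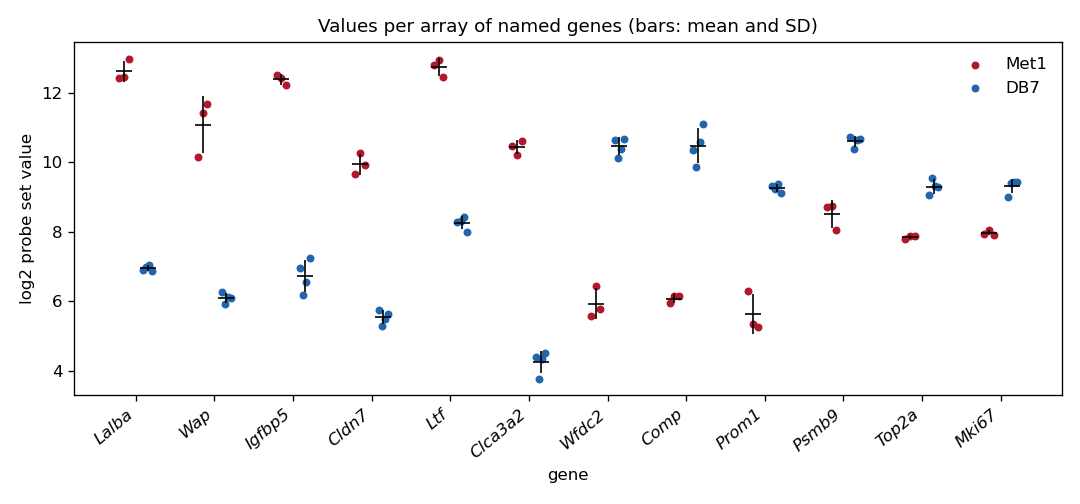
Log2 probe set values of 12 named genes (vertical axis) in each array, with Met1 in red (n = 3) and DB7 in blue (n = 4) and black bars for the mean and SD. The values of the groups do not overlap for any of the genes shown; Lalba lies near 12.61 in Met1 and 6.96 in DB7.

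Across the array, 3626 of 11704 tested probe sets differed between the lines, 1566 higher and 2060 lower in Met1 (limma, adjusted p under 0.05). At the level of genes, 2348 of 7482 differed, 986 higher and 1362 lower in Met1. Of these, 226 were at least 2-fold higher and 181 at least 2-fold lower. Values of the groups did not overlap for 39.4% of probe sets, where chance gives 5.71%. The median difference over all tested genes was -0.04. Of the genes named here, Sectm1a, St6galnac2, Birc5, Rsad2, Itgb4, Fasn, Fos, Dnajb9, Timp2 and Foxa1 lie in runs of neighbouring genes with a shifted median, and Foxa1 was lower in Met1 at the end of a run in which 49 genes were higher and 6 lower.

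Cell cycle genes were lower in Met1. Of 22 tested members of the proliferation list, 21 fell, 0 rose and Ccne1 did not pass (difference 0.00); adjusted over the list alone, 21 fell. Birc5, the inhibitor of apoptosis survivin that peaks in mitosis, fell by 2.00 (SE 0.13; adjusted p = 1.15e-05) and Ccna2, cyclin A2, fell by 1.42 (SE 0.10; adjusted p = 1.65e-05). Top2a, the topoisomerase of dividing cells, was 2.72-fold lower and Mki67, the Ki-67 antigen, 2.55-fold lower. The list's median difference was -0.80, past the threshold in camera (adjusted p = 1.07e-10) but not with an estimated correlation (adjusted p = 0.494 with an estimated correlation). The groups did not overlap in the list's mean (exact permutation p = 0.0286, the smallest possible, and 0.122 adjusted over the 30 lists). Without the arrays DB7 1 and DB7 4, 20 members fell.

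Milk and alveolar secretion genes were higher in Met1, with 8 of 9 tested members rising, both over all genes and adjusted over the list alone. Besides Lalba and Wap, Xdh, the xanthine dehydrogenase of the milk fat globule, rose 3.45-fold and Btn1a1, butyrophilin, rose 6.73-fold (limma, adjusted p = 7.15e-06 and 1.24e-05). Stat5a, the transcription factor that carries the prolactin signal, rose 1.77-fold, and the caseins Csn3 and Csn1s1 rose 2.67-fold and 2.35-fold. Mfge8 differed by -0.38 (SE 0.18) and did not pass. The other 5 of the 14 listed genes were not tested because they did not pass the intensity filter, among them the beta-casein gene Csn2, whose probe sets differed by 0.61 (SE 0.46) and 0.14 (SE 0.18). Glycam1, also among them, went the other way (-1.21, SE 0.65). This came from DB7 1 (8.58) and DB7 4 (7.11), against 5.38 to 5.61 in every other array. Wap and Btn1a1 lay below the array medians in DB7 (6.11 and 5.88) and passed the filter through their Met1 values, so the count of rises depends in part on the filter. The list's median difference was 1.41 (camera adjusted p = 4.63e-07; adjusted p = 0.0683 with an estimated correlation; exact permutation p = 0.0286).

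Luminal epithelial genes moved in both directions. Of 16 tested members, 4 rose and 7 fell, likewise adjusted over the list alone. Gata3 and Elf5, transcription factors of the luminal lineage, rose 2.99-fold and 2.76-fold, and the mucin gene Muc1 rose 3.13-fold. The luminal keratin Krt18 was 2.01-fold lower in Met1 at 11.54 ± 0.20 (SD, n = 3), and Krt7 was 3.45-fold lower. Spdef and Foxa1, also luminal transcription factors, fell 2.33-fold and 2.2-fold. Krt8 fell by 0.32 (SE 0.11; limma, adjusted p = 0.0466), a call lost under median centring (adjusted p = 0.0977). The list's median was -0.18 and its mean 0.09; camera gave a downward and fry an upward direction, with adjusted p of 0.839 and 0.363. Of 7 tested basal and myoepithelial genes, 4 rose and 0 fell, likewise adjusted over the list alone. Itgb4, an integrin of hemidesmosomes, rose 3.06-fold, Lamb3, a laminin chain, 2.85-fold, Itga6 1.36-fold and Egfr 1.3-fold, with probe sets of Egfr between 0.01 and 1.20. Krt5, the basal keratin, differed by 0.17 (SE 0.08; adjusted p = 0.132). The basal list passed in camera (adjusted p = 0.00188), but not with an estimated correlation (adjusted p = 0.245 with an estimated correlation).

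Genes of MHC class I antigen processing were lower in Met1: 9 of 10 tested members fell, also adjusted over the list alone. The immunoproteasome subunit genes Psmb9 and Psmb8 were 4.28-fold and 3.05-fold lower (limma, adjusted p = 4.68e-05 and 0.000531). Tap1, a subunit of the peptide transporter, was 2.19-fold lower and Erap1, a peptide-trimming protease, 1.77-fold lower. The list's median difference was -0.70 (camera adjusted p = 0.000839; adjusted p = 0.909 with an estimated correlation; exact permutation p = 0.0286). Without DB7 1 and DB7 4, 5 members fell, while the list's median was -0.71 (camera adjusted p = 0.00746). Of 6 MHC class II genes, H2-DMa, a chaperone of class II peptide loading, fell 2.26-fold, and H2-Eb1, H2-Aa and Cd74 differed by -0.34, -0.56 and -0.51 without passing. The class II list did not pass in camera (adjusted p = 0.235). B cell genes were high in DB7 1 and DB7 4 beside these values: Jchain, the joining chain of secreted immunoglobulins, measured 8.33 and 9.33 there and 5.08 to 5.88 in the other 5 arrays.

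Interferon-responsive genes differed in both directions. Cxcl9, a chemokine induced by interferon gamma, was 6.02-fold lower in Met1 (limma, adjusted p = 3.37e-05), Cxcl10 1.74-fold and Gbp2 1.71-fold lower. Rsad2, the antiviral protein viperin, rose 2.53-fold, Oas2 1.96-fold and Ifit1 3.62-fold (adjusted p = 0.00461, 0.0312 and 0.0485). The call of Oas2 was lost in 5 and that of Ifit1 in 6 of the 7 fits that left out a single array, with adjusted p up to 0.126 without Met1 2 and 0.153 without Met1 1. Thus 3 of 16 members rose and 3 fell, likewise adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.512). The list's median was 0.48 and camera's direction upward, whereas fry's was downward. The mean over 18 measured members was 8.14 in DB7 1 and 6.92 to 7.12 in the other DB7 arrays. Without it the list's median was 0.91 (camera adjusted p = 0.00394), and without DB7 1 and DB7 4, 9 members rose and 3 fell (camera adjusted p = 0.00695). Because DB7 1 had the highest DB7 mean of this list, leaving it out raises Met1 minus DB7 by construction. These passes are therefore no independent support for a rise in Met1.

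Collagen and other stromal genes varied between the DB7 arrays. Of 19 tested fibroblast and fibrillar matrix genes, 0 passed limma's threshold over all genes or adjusted over the list alone, and 3 lay above 0 at an unadjusted p under 0.05. The smallest p-values were those of the surface glycoprotein gene Thy1 (difference 0.38, SE 0.15), the collagens Col6a2 (0.64, SE 0.26) and Col5a2 (0.81, SE 0.35) and the matrix protein gene Postn (0.79, SE 0.40). The list passed narrowly in camera (median 0.52, adjusted p = 0.046), not with an estimated correlation (adjusted p = 0.955 with an estimated correlation), and the call was lost without Met1 2 (0.256), Met1 3 (0.094), DB7 2 (0.167) or DB7 3 (0.289), under quantile normalization (0.0955), under median centring (0.104), under the stricter filter (0.0996) and in fry (0.515). Its mean was 9.16 in DB7 1 and 8.61 in DB7 4, against 7.99 and 7.70 in DB7 2 and DB7 3 and 8.47 to 9.04 in Met1. Without DB7 1 and DB7 4, 16 of the 19 rose, with a median of 1.10. Of 10 endothelial genes 0 passed in limma, adjusted over all genes or over the list alone, and 0 at an unadjusted p under 0.05 (Plvap 0.48, SE 0.24; Cdh5 0.28, SE 0.21), while without these 2 arrays 4 rose. Among 17 macrophage genes Arg1, arginase 1, fell 5.28-fold and Cd14, the lipopolysaccharide co-receptor, rose 2.18-fold (limma, adjusted p = 8.12e-06 and 0.000473). The other 15 did not pass. Without the 2 arrays, 8 of the 17 rose, Cd14 among them, and 1 fell. Mylk, a myosin kinase, and Rgs5, a pericyte marker, rose 1.56-fold and 1.53-fold among 7 pericyte and smooth muscle genes. Scd1, a fatty acid desaturase, rose 1.45-fold among 7 adipocyte genes, although its other probe set differed by -0.0018. Adjusted over each list alone, these counts were equal. The endothelial, macrophage, pericyte and adipocyte lists did not pass in camera (adjusted p = 0.52, 0.506, 0.109 and 0.459) but did without the 2 arrays (0.0139, 0.00318, 0.0218 and 0.0487), and the pericyte list did without DB7 1 (0.0355). DB7 1 and DB7 4 had the 2 highest DB7 means of each of these lists and of the fibroblast list. For endothelial genes these were 7.07 and 6.86, against 6.48 and 6.56 in DB7 2 and DB7 3. Leaving these arrays out, a choice made after the data had been seen, raises Met1 minus DB7 by construction, so these passes are no independent support.

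**Figure D2:**
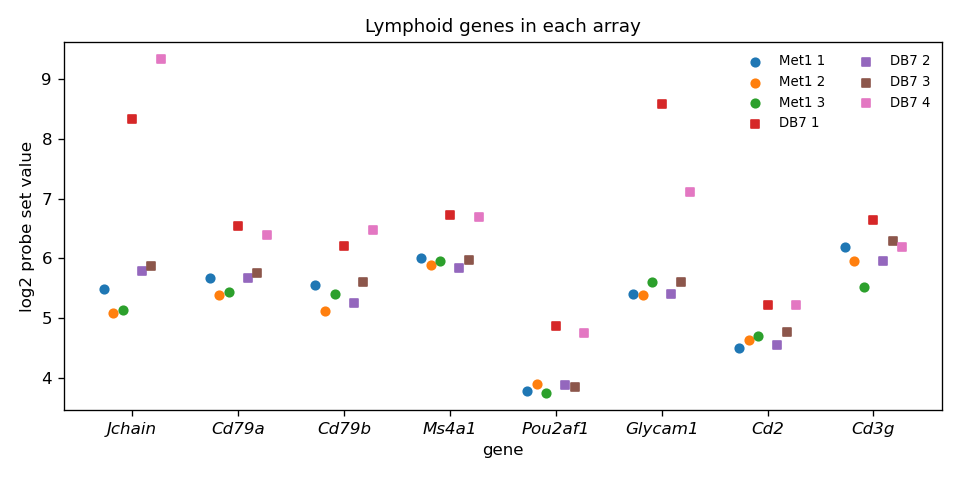
Log2 probe set values (vertical axis) of 8 lymphoid genes in each of the 7 arrays, with circles for Met1 and squares for DB7. DB7 1 and DB7 4 lie above the other 5 arrays for Jchain, Cd79a, Cd79b, Ms4a1, Pou2af1, Glycam1 and Cd2.

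Few markers of other cell types passed the intensity filter. Of 4 tested T and NK cell genes, Cd3d fell by 0.42 (SE 0.14; limma, adjusted p = 0.0446), a call lost when adjusted over the list alone. Of 3 B cell genes 0 passed in limma, over all genes or adjusted over the list alone, and 1, Blk (-0.22, SE 0.09), lay below 0 at an unadjusted p under 0.05; Ighm, the heavy chain of immunoglobulin M, differed by -0.99 (SE 0.52). Ltf, also a milk protein, was the only neutrophil list member of 3 to pass. In the skeletal muscle list Eno3 fell 2.89-fold, Mb rose 1.43-fold and Tnni2 differed by -0.07. The single keratinocyte and red blood cell genes tested, Lor and Alas2, differed by -0.21 (SE 0.09) and 0.01 (SE 0.13); Lor passed adjusted over the list alone. None of these lists passed in camera, where the smallest adjusted p was 0.0605 for the neutrophil list and those of the B, T and skeletal muscle lists were 0.544, 0.998 and 0.976. The neutrophil list passed without Met1 3 (0.0312), without DB7 1 (0.0381), without DB7 1 and DB7 4 (0.0368), in fry (0.000699) and under the stricter filter (0.0404), where Ltf was its only tested member. The T and NK list's median was -0.03 and camera's direction upward.

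Metabolic genes differed in both directions. Fasn, fatty acid synthase, rose 4.16-fold in Met1 and Srebf1, its regulator, 2.51-fold (limma, adjusted p = 4.13e-05 and 0.000377), whereas Fdft1, the squalene synthase of the cholesterol pathway, was 2.13-fold lower and Scd2 2.04-fold lower. Of 16 members of the cholesterol and fatty acid list, 3 rose and 7 fell (9 adjusted over the list alone). In the hypoxia and glycolysis list, 8 of 16 fell and 1 rose (9 and 2 adjusted over the list alone). Pfkfb3, a regulator of glycolysis, was 2.6-fold lower, Bnip3 2.15-fold and Pfkp 1.81-fold lower, while Car9, a carbonic anhydrase induced by hypoxia, was 2-fold higher. Of 22 oxidative phosphorylation genes, 11 fell and 1 rose, likewise adjusted over the list alone. Atp5b, Ndufs1 and Atp5a1 fell by 0.44, 0.54 and 0.40, and Cs, citrate synthase of the citric acid cycle, rose by 0.50, although another of its probe sets differed by -0.06. That list passed in camera (median -0.37, adjusted p = 0.00973) but not with an estimated correlation (adjusted p = 0.928 with an estimated correlation). The cholesterol and hypoxia lists did not pass in camera (adjusted p = 0.281 and 0.152). The first passed without DB7 1 (0.0355) and the second without the intensity filter (0.0461) and without DB7 1 and DB7 4 (0.0265). DB7 1 had the lowest DB7 mean of the cholesterol list, and DB7 1 and DB7 4 the lowest of the hypoxia list, which favours falls without them.

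Signalling and stress genes changed individually. Of 17 immediate early and feedback genes of the MAPK pathway, 2 rose and 4 fell. Fos rose 2.61-fold, and Etv4, Spred2 and Dusp6, the last a phosphatase of ERK, were 1.59-fold, 1.71-fold and 2.04-fold lower in Met1 (limma, adjusted p = 0.000136, 0.000338, 0.00229 and 0.00527). Of 11 FOXO-induced genes 4 rose and 0 fell, led by Fbxo32 (1.61-fold), Cited2 (1.89-fold), Txnip (2.17-fold) and Sesn3 (1.45-fold). The call of Sesn3 was lost in 6 of the 7 fits that left out a single array. Of 15 genes of the unfolded protein response, 5 rose and 4 fell. Dnajb9, a chaperone of the endoplasmic reticulum, rose 2.81-fold and Xbp1, a transcription factor of secretory cells, 2.03-fold. Ddit3 fell by 0.48, and Dnajc3 fell by 0.62 by its brightest probe set, with another at 0.18. Adjusted over each list alone, 1 more gene of the unfolded protein response fell, making 5, and the other counts were equal. These lists did not pass in camera (adjusted p = 0.998, 0.316 and 0.498), and the MAPK list's median was 0.01 and its mean -0.03.

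Genes linked to invasion differed in both directions. Of 7 tested genes of the mesenchymal transition list, Foxc2 and Tgfb1 were 3.28-fold and 1.77-fold lower in Met1 and Tgfb3 was 3.01-fold higher (limma, adjusted p = 3.32e-05, 0.00455 and 0.000307). Fn1, the matrix protein fibronectin, differed by 0.52 (SE 0.35). Without DB7 1 and DB7 4, 4 members of that list rose and 2 fell, with Fn1 at 1.12 (adjusted p = 0.00555). Of 14 extracellular proteases and inhibitors, Ctsl, Adamts1 and Ctsd rose 2.04-fold, 1.78-fold and 1.56-fold and Mmp14, a membrane-bound matrix metalloproteinase, was 1.57-fold lower. Of 13 integrin and adhesion genes 3 rose and 4 fell; Lgals3, galectin-3, was 2.39-fold, Cadm1 1.64-fold and the hyaluronan receptor Cd44 1.6-fold lower. Among 13 chemokines and growth factors, Hbegf, Vegfa and Tgfa were 1.34-fold, 1.65-fold and 1.37-fold lower and Cxcl14 was 1.54-fold higher, with 1 rising and 4 falling in all. Adjusted over each list alone, these counts were equal. The calls of Hbegf, Vegfa, Tgfa and Cxcl14 were lost in 2, 4, 5 and 5 of the 7 fits that left out a single array. Those of Ctsd and Mmp14 were lost in 1 and 2 of these fits. The camera adjusted p-values of these lists were 0.998, 0.315, 0.976 and 0.777, and the proteases passed without DB7 1 (0.0355) and without DB7 1 and DB7 4 (0.0139). In the latter case 7 of the 14 proteases and inhibitors rose and 0 fell, with Mmp14 at -0.45 (adjusted p = 0.0577). DB7 1 and DB7 4 had the highest DB7 means of the protease and mesenchymal lists, which favours rises without them. The mesenchymal list had a median of 0.16 and a downward direction in camera, and the integrins a mean of -0.02 and an upward one.

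Of 9 tested genes named as metastasis modifiers in mouse crosses, 0 rose and 4 fell over all genes, and 1 rose and 4 fell adjusted over the list alone. Tpx2, a spindle assembly factor, was 2.01-fold lower in Met1 (limma, adjusted p = 5.68e-05), and Cnot2 and Nup210 were 1.26-fold and 1.42-fold lower. Sipa1, a Rap GTPase-activating protein, measured 7.07 ± 0.03 in Met1 and 7.10 ± 0.23 in DB7 (SD, n = 3 and 4), a limma difference of -0.03 (SE 0.12; adjusted p = 0.888) whose sign was positive under quantile normalization (0.0030). Rrp1b differed by 0.27 (SE 0.10; adjusted p = 0.0623), and its tested probe sets ranged from -0.11 to 0.28. It passed under quantile normalization (0.0442), median centring (0.0422) and array weights (0.0285), and its adjusted p lay between 0.0622 and 0.236 under the other alternatives. Among 12 metastasis suppressors, Cd9, a tetraspanin, and Nme2, a nucleoside diphosphate kinase, were 1.76-fold and 1.28-fold lower. Timp2 and Pebp1 differed by -0.45 (SE 0.18) and 0.21 (SE 0.11) without passing. Adjusted over the list alone, the suppressor counts were equal. Neither list passed in camera (adjusted p = 0.445 and 0.583), whereas the modifier list passed in fry, in the downward direction (adjusted p = 0.0161). Among the 133 genes named by the fixed rule, 13 calls were lost when some single array was left out: Cd3d, Cnot2, Ctsd, Cxcl14, Hbegf, Krt8, Mmp14, Nme2, Nup210, Rgs5, Sesn3, Tgfa and Vegfa, with the highest adjusted p for Cd3d without Met1 2 (0.174).

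**Figure D3:**
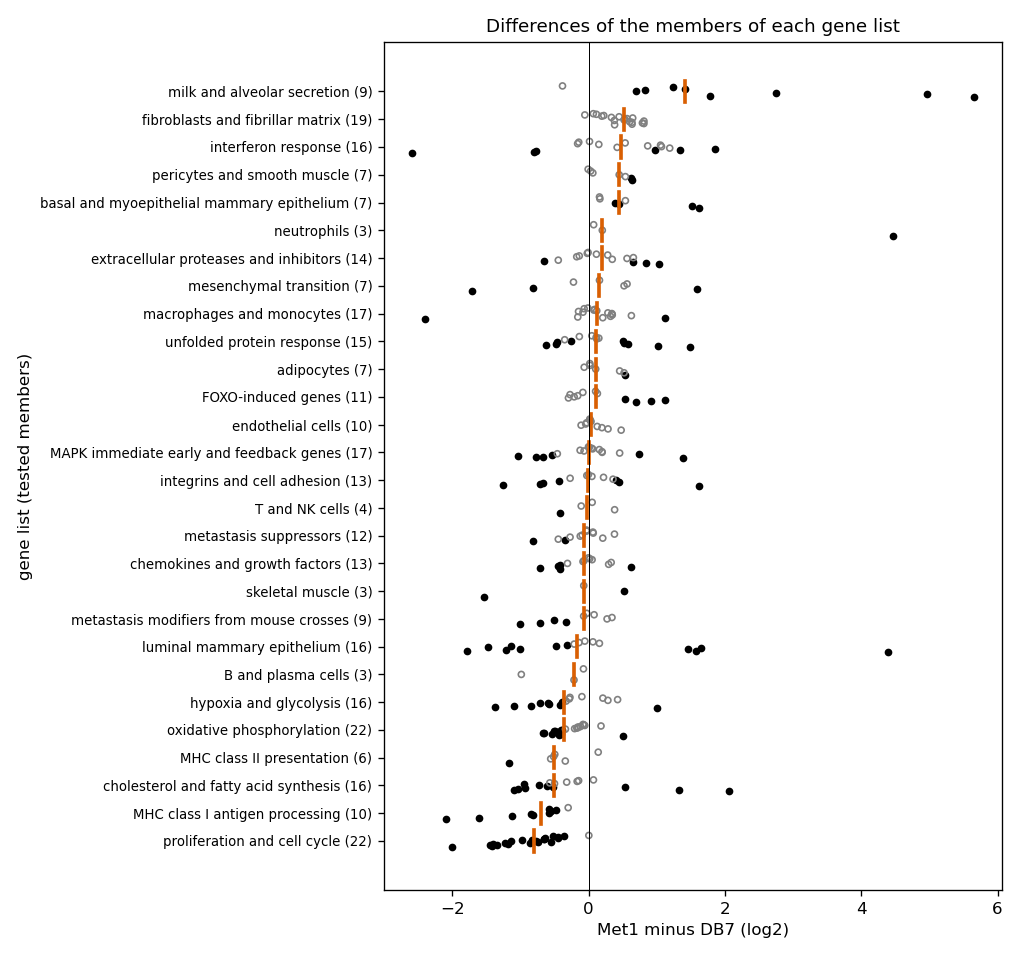
Met1 minus DB7 difference on the log2 scale (horizontal axis) of each tested member of the lists with at least 3 tested members (vertical axis, number tested in brackets); filled points passed limma's adjusted threshold, open points did not, and orange bars are medians. The medians run from -0.80 for proliferation to 1.41 for milk and alveolar secretion.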

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

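Of the tests in this part, those on the T and B cell markers were set down before their results were seen; the one without Thy1 was chosen afterwards. Among 165 named genes, list means and control measures examined in the 4 DB7 arrays, 7 had 1 array far from the rest by Dixon's test, which divides that array's gap by the group's range. Chance marks about 1 in 20 such groups, so 7 of 165 is no more than chance gives. DB7 4 stood apart for Pglyrp1 (10.64 against 11.19 to 11.25, share 0.905), Eno3 (8.49 against 7.57 to 7.66, share 0.909) and Srebf1 (10.35 against 9.84 to 9.89, share 0.905). DB7 1 stood apart for Mki67 (8.995 against 9.39 to 9.44, share 0.900) and the mean of the interferon response list (8.14 against 6.92 to 7.12, share 0.830). DB7 2 stood apart for Cx3cr1 (6.63 against 6.86 to 6.90, share 0.851) and Csf3r (7.19 against 7.46 to 7.50, share 0.868).

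Immunoglobulin and Glycam1 signal was high in DB7 1 and DB7 4. Glycam1, a milk gene that high endothelial venules of lymph nodes also express, measured 8.58 and 7.11 there against 5.38 to 5.61 elsewhere. The 7 B cell markers other than immunoglobulin genes averaged 6.66 and 6.77 in these arrays and at most 5.90 in the others, a margin of 0.762 against an SD of 0.14, which argues against sequence shared between immunoglobulin probe sets. Jchain, Cd79a, Cd79b, Ms4a1 and Pou2af1 were each higher in both arrays than in the others. Blk and Cd22 were not: Blk was highest in DB7 3 (7.07), and Cd22 was lower in DB7 4 (6.95) than in DB7 3 (7.12). The mean of 17 T and NK cell genes was also higher in both arrays than in the other 5, by 0.0706 against an SD of 0.06, but without Thy1, which the fibroblast list also holds, the margin was 0.0356 against an SD of 0.08, within the spread. The test therefore leaves open whether these 2 samples held lymphoid tissue such as a lymph node of the mammary fat pad, B and plasma cells alone, or a different immune response. The design names no biological difference between these arrays and the other DB7 arrays that could be tested.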

How the results depend on the processing

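The number of differing genes (2348) ranged from 1620 to 2464 and that of probe sets (3626) from 2468 to 3802 when each array was left out in turn. Lists past the threshold (6) ranged from 5 to 11, the 11 without DB7 1, and the RNA integrity difference of the Gapdh controls ranged from -0.0561 to -0.0057. The stricter intensity filter called 2358 probe sets, having tested fewer. A 2-fold minimum left 638 probe sets and 407 genes. Camera with an estimated correlation called 0 of 30 lists; fry called 7. Without DB7 1 and DB7 4, an alternative chosen after the data were seen, 14 lists passed, while 2448 genes differed, 2004 of them shared with the full comparison; the cause was not tested. Under the remaining alternatives the counts of probe sets and genes stayed within 1.5 times the main ones. Median centring moved the share of calls higher in Met1 from 42.0% to 50.2%. With the replicate number as a block (replicate block), which leaves DB7 4 without a partner, 1774 genes and 2803 probe sets differed. Of the Met1 arrays, 0 of 3 correlated best with the DB7 array of their number, and deviations of same-numbered arrays correlated at -0.17, -0.05 and 0.02. These values gave no sign of a pairing, but 3 correlations of deviations from group means are too few to exclude one. The real division of the arrays was the only 1 of 35 to give as many probe sets (3626, highest other 112) and the only 1 to give as many genes (2348, highest other 105). A share of 1 in 35 is the smallest that this count allows. The other divisions mix the lines, which widens the spread within their groups, so their low counts do not exclude chance. For lists, 19 of 35 divisions gave at least 6, the highest other 15, so the number of lists passing in camera did not set the real division apart. Of 453 values of the 24 genes with the largest differences, 452 kept their call and direction, the exception being Ctse without probe sets open to cross-hybridisation (0.0014), where another probe set stands for the gene. The other sign changes among the named genes were of genes that did not pass: Sipa1 under quantile normalization (0.0030), median centring (0.00999), with single arrays left out (-0.114 to 0.0666, the latter without DB7 1) and without DB7 1 and DB7 4 (0.153), Alas2 with array weights (-0.0071), with the block (-0.0320), with single arrays left out (-0.136 to 0.141) and without DB7 1 and DB7 4 (-0.0089), and Tnni2 without Met1 2 (0.0074) or DB7 3 (0.0070). Over all genes called in both fits, 2 had opposite signs without probe sets open to cross-hybridisation, and 0 under each other alternative. Among the 133 named genes, calls were lost in 73 values outside the 2-fold minimum and gained in 35 of 2481. The pseudocount alternative was not run because the values are already logarithms. The variance models do not enter camera.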

Other observations

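The test on host cell lists below was chosen after the result had been seen; the other tests here were set down before, on patterns, and a chromosome, picked from the data. Several gland secretions not described above also differed, and were chosen after their values were seen. The secretoglobins Scgb2b27 and Scgb1b27, members of a family of close paralogs, were higher in Met1 by 3.04 and 2.67 on the log2 scale, with wide spreads (11.86 ± 0.33 against 8.82 ± 0.76, and 11.31 ± 1.03 against 8.64 ± 0.83; SD, n = 3 and 4). Pip, the prolactin-induced protein, was higher by 3.30, with 10.16 in Met1 3 and 7.85 and 8.17 in the other Met1 arrays. Lpo, the lactoperoxidase of milk and saliva, went the other way, at 6.75 ± 0.25 in Met1 and 9.15 ± 0.15 in DB7. Lrg1, an acute-phase glycoprotein, was higher in Met1 by 2.56, as Saa1 was.

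Along the gene order of GRCm38.p6, 123 of 7095 windows of 20 neighbouring tested genes had a median difference beyond 0.42, the limit that 95% of 1000 shuffled orders stayed within, which argues against chance order. With 1 gene per family stem, 87 windows lay beyond their limit, which argues against neighbouring family members. The windows formed 8 runs on 2 chromosomes. From Cep295nl to Metrnl, 37 of 52 genes were higher and 7 lower in Met1 (median 1.01). Shorter runs of both signs on that chromosome started before Cep295nl, and the runs there overlap in part, so they are not separate blocks. On the other chromosome, runs from Rab10 to Siva1 were mostly higher. The latter chromosome's 72 tested genes outside the runs also lay higher than genes of chromosomes without runs, by a median of 0.237 (0.086 to 0.388, 2 standard errors either side). A difference in copy number of that chromosome between the tumour lines is a candidate explanation that passed this test. The test cannot separate it from regional regulation that reaches past the edges of the runs, and its interval treats neighbouring genes as independent. The chromosome with the run from Cep295nl to Metrnl was not tested in this way. Expression also cannot show whether Met1 gained or DB7 lost material.

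Xist, the RNA that coats the inactive X chromosome, differed by -1.81 (7.73 ± 0.24 against 9.54 ± 0.15; SD, n = 3 and 4) and by -2.37 at its other tested probe set. The mean of 3 Y-linked genes differed by -0.0496 (95% interval -0.166 to 0.067), which argues against male tissue in the Met1 tumours. The lowest median among the endothelial, macrophage and fibroblast lists was 0.0293, which argues against a smaller share of host cells. Loss of the inactive X in Met1 tumour cells may account for it, but the mean of 6 genes that escape inactivation differed by -0.0077 (-0.226 to 0.211) and left this open: Eif2s3x, Kdm6a, Kdm5c, Pbdc1 and Ddx3x lay between -0.46 and -0.06, whereas Car5b, below the intensity filter, was higher by 1.57. Lower Xist transcription without loss of the chromosome stays open too.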
